A study of Homo sapiens
Mus musculus with 16 samples.

How the data were processed

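The study measured RNA from tumours that MDA-MB-231 cells, a human triple-negative breast cancer line, formed in nude mice after injection into the mammary fat pad. There were 4 treatments with 4 mice each, and 1 paired-end mRNA library per tumour, 16 in all. Tumour cells are human and host cells are mouse. Counts of human genes are therefore taken to stand for the tumour and counts of mouse genes for the host tissue within it. This assumes that reads were divided correctly between the species, which was not tested.

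The values are whole-number counts per gene, deposited by the authors as 2 matrices, 1 of human and 1 of mouse genes, each with the same 16 libraries. Trimmomatic 0.36, HISAT2 2.04, Picard, StringTie and edgeR and the genome builds hg38 and mm10 are named in the submitters' processing notes, with no order or role. How reads were divided between the species, whether duplicates were removed, whether strand was used and which annotation was counted are not given in the sources used here. The counts as deposited do not fall off evenly at the low end: in the human matrix the values 1, 2, 3 and 4 occur 14483, 24107, 24309 and 10534 times, and in the mouse matrix 9478, 15617, 17175 and 6776 times. A low count in these matrices is therefore not a plain tally of single reads, and 15 human and 38 mouse genes stand at 0 in 1 library of a group and at a count in 4 digits or more in another. Intervals and limits given for counts cover counting error only.

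The human matrix lists 58051 Ensembl gene IDs, of which 34750 have a count in at least 1 library; the mouse matrix lists 48795, of which 27338 do. The files do not pair these IDs with gene symbols, and the reference table at hand has no Ensembl IDs, so 0 human and 0 mouse IDs were matched. The 53 gene lists fixed before the data were examined could therefore not be tested, nor could the phenelzine and paclitaxel target genes be looked up. At most 2 IDs that rose and 2 that fell are printed, and the other genes are described as groups by level and direction. The rule for named genes, fixed before the data were examined, took for each comparison up to 5 genes with the largest rise and up to 5 with the largest fall among those past the threshold. It also asked for a mean of at least 5 CPM in the higher group, no overlap between the libraries of the 2 groups, and a gene symbol. The symbol condition, and the parts of the rule that named list members and drug targets, could not be applied. The choice of the 4 printed IDs, called in most comparisons and then largest in fold, was made after their values were seen. Whether they share reads with near-identical copies or overlapping genes was not assessed.

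Libraries are named by their group and number, and the combination is nab-paclitaxel plus phenelzine. Human totals ranged from 11.1 to 34.5 M counts and mouse totals from 3.46 to 27.4 M. The sum of both was 33.6 to 42.6 M. No library repeated another of its group. The chi-square per degree of freedom between libraries of a group was at least 43.8 for human and 14.0 for mouse genes, far above counting noise. Libraries of different groups were not compared in this way. No column of per-sample values was left unused.

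Each matrix was tested on its own with edgeR 4.0.16 in R 4.3.3: TMM factors, the default filter on low counts (minimum count of 10), a model with 1 mean per group over all 16 libraries (12 residual degrees of freedom) and the quasi-likelihood F test. All groups were fitted together so that they shared 1 estimate of the spread. Adjusted p-values are Benjamini-Hochberg values over the 18131 human or 15074 mouse genes tested, with a threshold of 0.05, and genes past it are said to have risen or fallen. Standard errors are the fold change divided by the square root of F. The p-values measure the spread between libraries, each from 1 mouse. The comparisons fixed before the data were examined were each drug and the combination against vehicle, the combination against each drug, and the interaction of the 2 drugs. The averages of each drug effect over both states of the other drug were added after the data were seen. CPM values of the printed IDs are scaled by TMM. The mouse share is the percentage of all counts of both matrices that lie in the mouse matrix. It was compared with exact permutation tests, all two-sided, adjusted over the 5 comparisons between groups. With 4 against 4 mice the smallest p such a test can give is 0.0286.

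Counts were simulated by draws around the mean of each gene over all 16 libraries, at the sizes of these libraries. In the nab-paclitaxel group 200 genes were changed. Among 17776 human genes, the test against vehicle recovered 42% of 2-fold, 70% of 4-fold, 82% of 8-fold and 94% of 16-fold changes. It made 6 false calls among 150. Among 14851 mouse genes it recovered 22%, 72%, 90% and 86%, with 3 false calls among 138. Both simulations gave 0 calls in the contrast of phenelzine with vehicle, which was left unchanged. The simulated libraries of a group differ only by such draws, unlike the real libraries with nab-paclitaxel. These rates therefore hold for the simulated case only.

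The alternatives fixed in advance were RLE size factors, no filter, a minimum count of 50, DESeq2 1.42.0, only the 2 groups compared, the replicate number as a block, the logit of the mouse share as a covariate, limma 3.58.1 voom with sample quality weights, and leaving out each library in turn. Leaving out 4 libraries that stand apart, other bounds for the genes gained, and the tests of 8 against 8 libraries were added after the data were seen. Other regroupings of the libraries were counted for each comparison, with 35 splits of 4 and 4 and 100 regroupings for the interaction and the averages. A smaller number of regroupings was drawn first for these last, before the full number; the values given are from the full draw. A scoring of cell-cycle phase was looked at and not used. Tables and plots were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.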

Results

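RNA was sequenced from MDA-MB-231 xenograft tumours in Balb/c nude mice to read tumour and host expression from the same tissue. Each mouse received 2 M cells in 50 µl, and tumours were excised on day 50. Groups of 4 mice received vehicle, nab-paclitaxel, phenelzine or both drugs. Nab-paclitaxel, an albumin-bound form of the microtubule-stabilising drug paclitaxel, was given at 30 mg/kg on days 15, 22 and 29. Phenelzine, an inhibitor of monoamine oxidases, was given at 40 mg/kg daily from day 15. Human totals in the vehicle group were 32.6, 23.7, 27.3 and 33.5 M counts for mice 1 to 4, and mouse totals 5.21, 14.4, 6.38 and 5.28 M. With nab-paclitaxel they were 15.4, 32.7, 32.0 and 23.8 M human and 22.9, 9.97, 8.53 and 17.2 M mouse counts. With phenelzine they were 34.5, 34.4, 33.9 and 30.2 M human and 3.82, 6.18, 3.46 and 5.81 M mouse counts. With the combination they were 11.1, 21.6, 15.996 and 28.8 M human and 27.4, 19.5, 20.3 and 6.60 M mouse counts.

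The mouse share of counts was taken as a measure of how much host RNA a tumour library held, provided reads were divided correctly. It was 21.1% ± 11.5 (SD, n = 4) with vehicle, 36.5% ± 18.1 with nab-paclitaxel, 12.7% ± 3.54 with phenelzine and 48.3% ± 22.1 with the combination. Single tumours varied widely. In mice 1 to 4 the share was 13.8%, 37.8%, 19.0% and 13.6% with vehicle, 59.7%, 23.4%, 21.1% and 41.9% with nab-paclitaxel, 9.97%, 15.2%, 9.25% and 16.1% with phenelzine, and 71.2%, 47.4%, 55.9% and 18.6% with the combination. The 95% Wilson intervals of these shares were at most 0.0323 percentage points wide, so counting error was small beside the spread between libraries; with 1 library per tumour, mice and library preparation cannot be separated.

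No comparison between 2 groups passed adjustment over the 5 comparisons (exact permutation tests, two-sided). The combination was 35.6 points above phenelzine, with exact p = 0.0286, the smallest possible, and adjusted p = 0.143. It was 27.2 points above vehicle, exact p = 0.0857 and adjusted p = 0.214. Nab-paclitaxel was 15.5 points above vehicle, exact p = 0.171 and adjusted p = 0.214. The difference of phenelzine from vehicle was -8.40 points, exact p = 0.171 and adjusted p = 0.214. The combination was 11.8 points above nab-paclitaxel, exact p = 0.457, also 0.457 after adjustment. Single libraries moved 3 of these differences by over 1.5 times. Nab-paclitaxel against vehicle was 7.74 points without nab-paclitaxel 1, and phenelzine against vehicle -2.81 points without vehicle 2. The combination against nab-paclitaxel was 4.12 points without combination 1, 6.61 without nab-paclitaxel 3, 7.39 without nab-paclitaxel 2, 19.5 without nab-paclitaxel 1 and 21.7 without combination 4. In a test added after the data were seen, the 8 libraries with nab-paclitaxel averaged 42.4% and the 8 without 16.9%, a difference of 25.6 points (exact permutation p = 0.00622, two-sided). The 8 libraries with phenelzine differed from the 8 without by 1.68 points (exact permutation p = 0.874), and by -4.14 to 6.1 points with 1 library left out. The phenelzine effects with and without nab-paclitaxel differed by 20.2 points (exact permutation p = 0.1996).

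**Figure D1:**
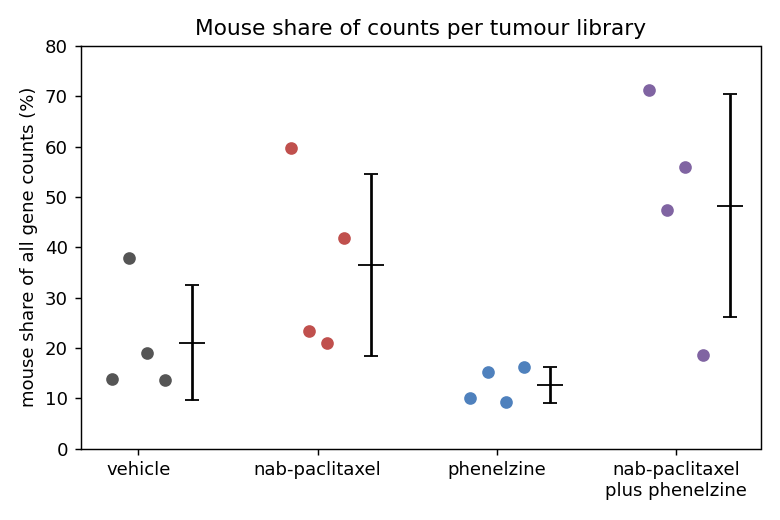
Mouse share of all gene counts (vertical axis, percent) for each tumour library, by treatment group, with points for single mice and bars beside them for the mean and SD of 4 mice. The phenelzine libraries lie between 9.25% and 16.1%, and the combination libraries between 18.6% and 71.2%.

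Libraries with nab-paclitaxel did not form 1 group by their human genes. The first principal component of log2 CPM held 48.7% of the variance. Nab-paclitaxel 1 and 4 scored 125 and 72.7 on it, and combination 1 and 3 scored 117.2 and 120.4. The other libraries with nab-paclitaxel scored -16.8 (nab-paclitaxel 2), 5.4 (nab-paclitaxel 3), -39.5 (combination 2) and -1.7 (combination 4). Vehicle libraries scored -56.6 to -43.6 and phenelzine libraries -53.3 to -38.9. These 4 libraries, which stood apart from the rest, had mouse shares of 59.7%, 41.9%, 71.2% and 55.9%, and the other 4 with nab-paclitaxel 23.4%, 21.1%, 47.4% and 18.6%. In the mouse genes the first component held 31.6% of the variance.

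**Figure D2:**
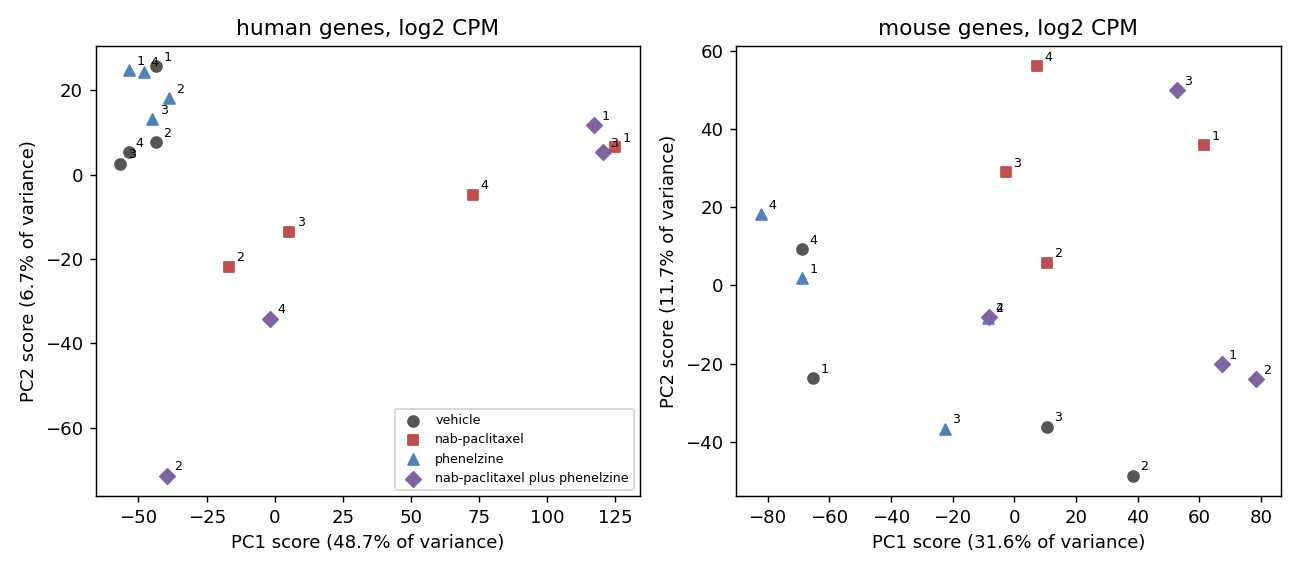
Scores of the 16 libraries on the first and second principal components of log2 CPM, human genes on the left and mouse genes on the right, with the percentage of variance on each axis, symbols for the treatment group and numbers for the mouse. In the human genes nab-paclitaxel 1 and 4 and combination 1 and 3 lie at 72.7 to 125 on the first component, apart from the rest.

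Nab-paclitaxel against vehicle asks what the taxane alone did to tumour and host. Of the human genes, 20 rose and 10 fell (edgeR quasi-likelihood test). Of the 20 that rose, 10 had a mean under 1 CPM in vehicle tumours, 14 rose over 4-fold, and the median log2 fold change was 3.65, or 3.28 with the 2 genes listed at 0 in every vehicle library set to their floor of 3 counts per library. Of the 10 that fell, 7 had a vehicle mean of at least 10 CPM, and the median log2 fold change was -1.87. ENSG00000137868 rose from 0.197 ± 0.138 to 115 ± 119 CPM (SD, n = 4 each), a log2 fold change of 9.22 (SE 1.63, edgeR adjusted p = 0.0426). Its values with nab-paclitaxel ran from 12.1 to 259 CPM. The call held without nab-paclitaxel 2 (edgeR adjusted p = 0.0239) and was lost without any 1 of the other 7 libraries, with adjusted p up to 0.166, while the log2 fold change stayed between 8.46 and 9.73. ENSG00000204388 fell from 258 ± 70.1 to 69.1 ± 22.8 CPM (SD, n = 4 each), log2 fold change -1.90 (SE 0.275, edgeR adjusted p = 0.0229); this call held without vehicle 3 (0.0463) or nab-paclitaxel 2 (0.00813) and was lost without any 1 of the other 6, with adjusted p up to 0.0824 and log2 fold changes of -2.12 to -1.70. The 4 libraries of 1 group did not overlap the 4 of the other in 2744 human genes, 15.1% of those tested, against 2.86% by chance. Of the mouse genes, 0 passed edgeR's threshold, with 1799 at an unadjusted p under 0.05. DESeq2 called 221 and voom with quality weights 1, and edgeR called 4 without vehicle 2 and 1 without vehicle 3 or nab-paclitaxel 1. The human count depended on single libraries: it was 0 without vehicle 1, vehicle 4 or nab-paclitaxel 4, 4 without nab-paclitaxel 1 or nab-paclitaxel 3, 3 without vehicle 2, 8 without vehicle 3 and 703 without nab-paclitaxel 2. DESeq2 called 1441 human genes and voom 599; 16 passed with the mouse share as a covariate. Without the 4 libraries that stood apart 26 passed, 10 of them among the 30, and in a fit of only the 2 groups 27, with 14 among the 30. With the replicate number as a block 0 passed (lowest edgeR adjusted p = 0.0699).

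Phenelzine against vehicle asks what this drug alone did. No gene passed in either species. In the human genes edgeR called 0, with 426 at an unadjusted p under 0.05, DESeq2 called 4 and voom 0. In the mouse genes edgeR called 0, with 921 at an unadjusted p under 0.05, DESeq2 called 11 and voom 0. The median absolute log2 fold change of human genes was 0.14, against 0.29 for nab-paclitaxel. ENSG00000204388 stood at 175 ± 52.4 CPM with phenelzine (SD, n = 4) and ENSMUSG00000055866 at 40.9 ± 9.20 CPM against 20.3 ± 5.51 with vehicle, log2 fold change 1.01 (SE 0.292, edgeR adjusted p = 0.773), neither past the threshold. Groups did not overlap in 2.89% of human and 2.02% of mouse genes, near the 2.86% given by chance. Without phenelzine 2 the counts were 1 human and 3 mouse genes, and without phenelzine 3 it was 1 mouse gene.

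The combination against vehicle asks what both drugs did together. Of the human genes, 97 rose and 36 fell (edgeR quasi-likelihood test). Of those that rose, 49 had a vehicle mean under 1 CPM and 65 rose over 4-fold, with a median log2 fold change of 3.38. Of those that fell, 28 had a vehicle mean of at least 10 CPM, with a median of -1.30. With the 7 genes listed at 0 in every vehicle library and the 2 listed at 0 in every combination library set to their floor, these medians were 3.27 and -1.25. ENSG00000137868 stood at 98.6 ± 121 CPM (SD, n = 4), log2 fold change 9.0 (SE 1.62, edgeR adjusted p = 0.0349), and ENSG00000204388 at 67.4 ± 17.3 CPM, log2 fold change -1.93 (SE 0.275, edgeR adjusted p = 0.0130). The first call held without combination 2 (edgeR adjusted p = 0.00872) or combination 4 (0.0287) and was lost without any 1 of the other 6, up to 0.130. The second was lost without vehicle 1 (edgeR adjusted p = 0.0705), combination 1 (0.0506) or combination 3 (0.0664). The log2 fold changes in these fits were 7.88 to 9.52 and -2.11 to -1.73. Single libraries decided the human count: 1 without vehicle 1, 2 without combination 3, 4 without vehicle 3 or vehicle 4, 8 without vehicle 2, 10 without combination 1, 557 without combination 4 and 1388 without combination 2. It was 1 with the mouse share as a covariate, 21 without the 4 libraries that stood apart, and 0 in a fit of only the 2 groups, while DESeq2 called 1574 and voom 111.

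In the host, 3 mouse genes rose and 2 fell with the combination against vehicle. ENSMUSG00000055866 rose from 20.3 ± 5.51 to 87.8 ± 32.1 CPM (SD, n = 4 each), log2 fold change 2.11 (SE 0.297, edgeR adjusted p = 0.0204), a call that held without vehicle 2 (0.0188) or combination 4 (0.00342) and was lost without any 1 of the other 6, up to 0.0980, at log2 fold changes of 1.96 to 2.32. ENSMUSG00000020522 fell from 57.8 ± 3.77 to 24.1 ± 6.66 CPM (SD, n = 4 each), log2 fold change -1.27 (SE 0.161, edgeR adjusted p = 0.0184). That call was lost without vehicle 1 (edgeR adjusted p = 0.0980), vehicle 3 (0.0599), vehicle 4 (0.0724), combination 1 (0.0605) or combination 3 (0.0673), at log2 fold changes of -1.45 to -1.14. The other genes that rose went from 12.99 ± 2.03 to 51.3 ± 11.7 CPM and from 13.9 ± 3.71 to 114 ± 59.5 CPM (SD, n = 4), and the other that fell from 11.9 ± 4.18 to 3.01 ± 0.986 CPM. The count was 0 without vehicle 1, vehicle 3, vehicle 4, combination 1 or combination 3, 2 without combination 2, 8 without vehicle 2 and 58 without combination 4. It was 0 in the fit of only the 2 groups and without the 4 libraries that stood apart, while DESeq2 called 325 and voom 3. With the mouse share as a covariate 1 gene passed, and 0 of the 5 calls were kept.

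The combination against nab-paclitaxel asks what phenelzine added to the taxane. Of the human genes, 0 rose and 1 fell (edgeR quasi-likelihood test), with 533 at an unadjusted p under 0.05, while DESeq2 called 10 and voom 0, and groups did not overlap in 1.54% of genes against 2.86% by chance. The gene that fell was listed at 0 in all 4 combination libraries, where a count of 0 allows up to 0.271 CPM in the smallest of them, and at 0.754 to 2.44 CPM with nab-paclitaxel. Without combination 4 the human count was 0. In the host, ENSMUSG00000055866 rose from 17.2 ± 4.97 to 87.8 ± 32.1 CPM (SD, n = 4 each), log2 fold change 2.36 (SE 0.298, edgeR adjusted p = 0.00857). The call was lost without nab-paclitaxel 1 (edgeR adjusted p = 0.0593) or nab-paclitaxel 4 (0.0617), at log2 fold changes of 2.18 to 2.54 over the libraries left out. ENSMUSG00000020522 fell from 61.7 ± 5.80 to 24.1 ± 6.66 CPM, log2 fold change -1.36 (SE 0.161, edgeR adjusted p = 0.00755), and 1 further mouse gene fell from 51.5 ± 5.42 to 17.8 ± 3.33 CPM. The mouse count was 1 without nab-paclitaxel 1 or 4 and 5 without combination 4, and 0 without the 4 libraries that stood apart. With the mouse share as a covariate 1 of these genes passed, and it fell. The call of ENSMUSG00000055866 was thus lost there. The fit of only the 2 groups called 1 mouse gene, none of these 3 (edgeR adjusted p = 0.189 for both IDs), while DESeq2 called 46 and voom 10.

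The combination against phenelzine asks what nab-paclitaxel added to phenelzine. Among human genes, 299 rose and 113 fell (edgeR quasi-likelihood test). Of those that rose, 134 had a mean under 1 CPM with phenelzine and 188 rose over 4-fold, with a median log2 fold change of 2.76. Of those that fell, 91 had a mean of at least 10 CPM with phenelzine, with a median of -0.84. ENSG00000137868 rose from 0.216 ± 0.0685 CPM (SD, n = 4), log2 fold change 8.81 (SE 1.58, edgeR adjusted p = 0.0272), and ENSG00000204388 fell, log2 fold change -1.38 (SE 0.271, edgeR adjusted p = 0.0319). Both calls held without combination 2 (edgeR adjusted p = 0.00615 and 0.0211) or combination 4 (0.0216 and 0.0239) and were lost without any 1 of the other 6, up to 0.0949 and 0.0994, at log2 fold changes of 7.68 to 9.23 and -1.56 to -1.17. In the host 1 gene changed, ENSMUSG00000020522, which fell from 66.7 ± 6.95 to 24.1 ± 6.66 CPM (SD, n = 4 each), log2 fold change -1.48 (SE 0.162, edgeR adjusted p = 0.00307). Groups did not overlap in 10.9% of human and 11.2% of mouse genes, against 2.86% by chance. The human count was 7 without phenelzine 1 or phenelzine 4, 10 without combination 1, 12 without combination 3, 15 without phenelzine 2, 79 without phenelzine 3, 834 without combination 4 and 1487 without combination 2; the mouse count was 5 without phenelzine 2, 2 without phenelzine 3 and 389 without combination 4. With the mouse share as a covariate 3 human and 0 mouse genes passed, and without the 4 libraries that stood apart 46 human and 0 mouse genes, so the call of ENSMUSG00000020522 ended in both (edgeR adjusted p = 0.554 and 0.638). In the fit of only the 2 groups 1 human gene passed, and the call of ENSMUSG00000020522 was lost (edgeR adjusted p = 0.0914). DESeq2 called 1832 human and 563 mouse genes and voom 126 and 391, and 2726 mouse genes had an unadjusted p under 0.05 in edgeR.

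The interaction asks whether the effect of the combination differed from the sum of both drugs on the log scale. No gene passed. For human genes edgeR called 0, with 544 at an unadjusted p under 0.05, DESeq2 called 11 and voom 0. For mouse genes edgeR called 0, with 1228 at an unadjusted p under 0.05, DESeq2 called 18 and voom 1. ENSMUSG00000020522 had an interaction of -1.57 on the log2 scale (SE 0.226, edgeR adjusted p = 0.0775), short of the threshold, and ENSMUSG00000055866 one of 1.35 (SE 0.408, edgeR adjusted p = 0.597). Without nab-paclitaxel 4 the human count was 1, and the mouse count was 4 without phenelzine 2 and 1 without phenelzine 3 or combination 4.

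**Figure D3:**
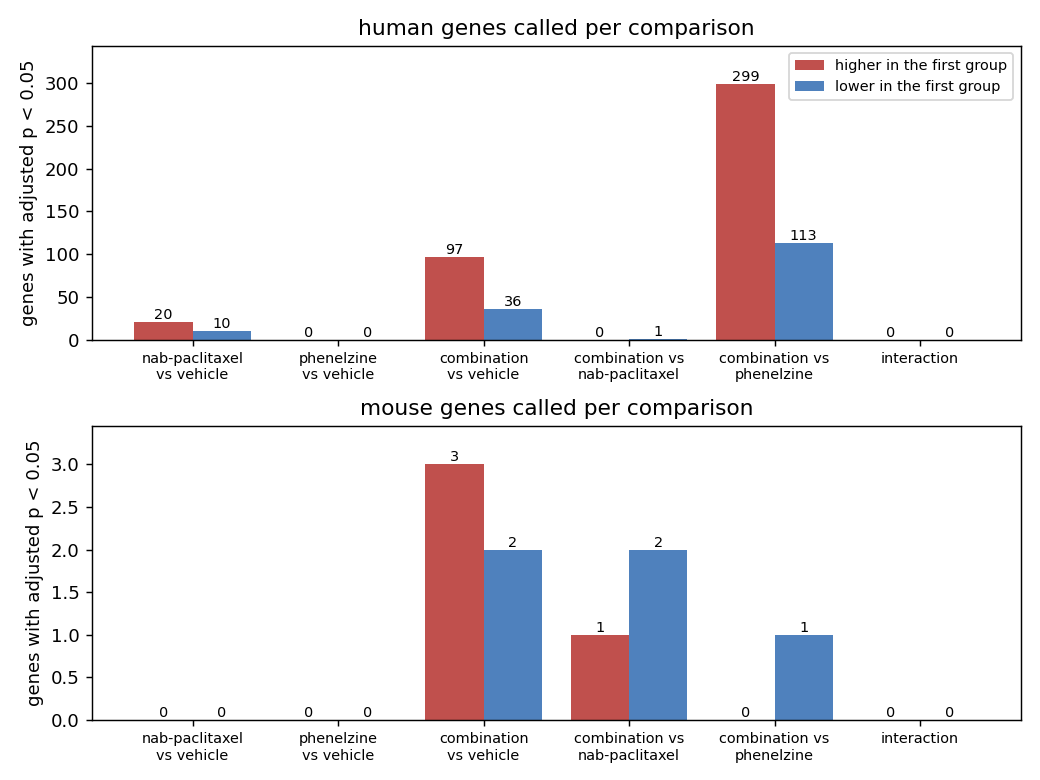
Number of genes with an adjusted p under 0.05 (vertical axis) in each planned comparison, human genes above and mouse genes below, with red bars for genes higher in the first group and blue bars for those lower. Counts are largest for the combination against phenelzine in the human genes, with 299 higher and 113 lower, and at most 5 for any comparison in the mouse genes.

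The nab-paclitaxel effects with and without phenelzine had the same sign in most of the human genes called in either. The effect against vehicle and the effect of adding it to phenelzine come from different libraries, and their fold changes correlated across 18131 genes with r = 0.773 (Spearman 0.665), genes not being independent replicates. All 30 genes called against vehicle, and 400 of the 412 called on top of phenelzine, had the same sign in the other comparison. Of these, 15 rose in both, where independent lists would share 0.330, and 6 fell in both, where they would share 0.0623. Each of the 2 treated groups holds 2 of the 4 libraries that stood apart, and without these r was 0.333 (Spearman 0.222), with the same sign in 29 of the 30 genes and 374 of the 407 still tested. Without a filter on low counts r was 0.369. The phenelzine effects with and without nab-paclitaxel correlated at -0.0407 in the human genes.

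The average effect of nab-paclitaxel over both phenelzine states, a contrast added after the data were seen, set 8 libraries against 8. Among human genes, 2030 rose and 1101 fell (edgeR quasi-likelihood test). Of those that rose, 842 had a reference mean under 1 CPM and 711 rose over 4-fold, with a median log2 fold change of 1.44. Of those that fell, 899 had a mean of at least 10 CPM, with a median of -0.50. Among mouse genes, 49 rose, with a median of 1.36, and 71 fell, with a median of -1.06. The human count moved by over 1.5 times without nab-paclitaxel 1 (1855), nab-paclitaxel 4 (1979), combination 3 (1881) and combination 2 (4909). It was 27 with the mouse share as a covariate and 305 without the 4 libraries that stood apart. The mouse count was 14 without nab-paclitaxel 1, nab-paclitaxel 4 or phenelzine 1, 15 without combination 3, 21 without phenelzine 3, 27 without combination 1, 39 without vehicle 4, 40 without nab-paclitaxel 3, 44 without vehicle 1, 47 without combination 2, 53 without phenelzine 4, 70 without vehicle 3, 257 without nab-paclitaxel 2, 715 without vehicle 2 and 830 without combination 4. It was 1 with the mouse share as a covariate and 0 without the 4 libraries that stood apart, while DESeq2 called 1299 and voom 898.

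The average effect of phenelzine over both nab-paclitaxel states, also added later, was confined in edgeR's test to 4 mouse genes. The sample names of a group run together. Here and in the other comparisons, handling or collection that differed by group cannot be told apart from treatment. ENSMUSG00000055866 averaged 64.4 CPM in the 8 libraries with phenelzine and 18.7 in the 8 without, log2 fold change 1.68 (SE 0.208, edgeR adjusted p = 0.00648). The other 3 averaged 41.8 against 14.3 CPM, 85.0 against 17.0 CPM and, the 1 that fell, 18.6 against 46.2 CPM. Of the 4 genes, 3 were also called for the combination against vehicle and 2 for it against nab-paclitaxel, each in the same direction. These comparisons share libraries. Over all mouse genes tested, the 8 and 8 libraries did not overlap in 4, or 0.0265%, against 0.016% by chance. Among these 4 were 2 of the called genes that rose and the 1 that fell. The number of genes called was 8 without phenelzine 2, 7 without combination 4 and 1 without the 4 libraries that stood apart. DESeq2 called 23 and voom 7. In the human genes edgeR called 0, with 399 at an unadjusted p under 0.05; DESeq2 called 8 and voom 0. Without nab-paclitaxel 4 or combination 2 the human count was 1.

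A group of human genes was near 0 in every tumour without nab-paclitaxel and high in some with it. There were 84 genes at or under 1 CPM in all 8 libraries without nab-paclitaxel and at 10 CPM or more in at least 1 with it, and 5 in the reverse direction; the definition was set after the data were seen. Their median was 16.3, 0.735, 1.75 and 8.06 CPM in nab-paclitaxel 1 to 4 and 12.2, 0.325, 16.2 and 1.01 CPM in combination 1 to 4, against 0.101 to 0.262 CPM in the other 8 libraries. They reached 10 CPM in 69, 2, 5 and 31 genes in nab-paclitaxel 1 to 4 and in 55, 0, 71 and 0 genes in combination 1 to 4. With other bounds the counts were 46 against 4 (0.5 and 10 CPM), 49 against 4 (1 and 20 CPM) and 19 against 4 (0.2 and 10 CPM).

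**Figure D4:**
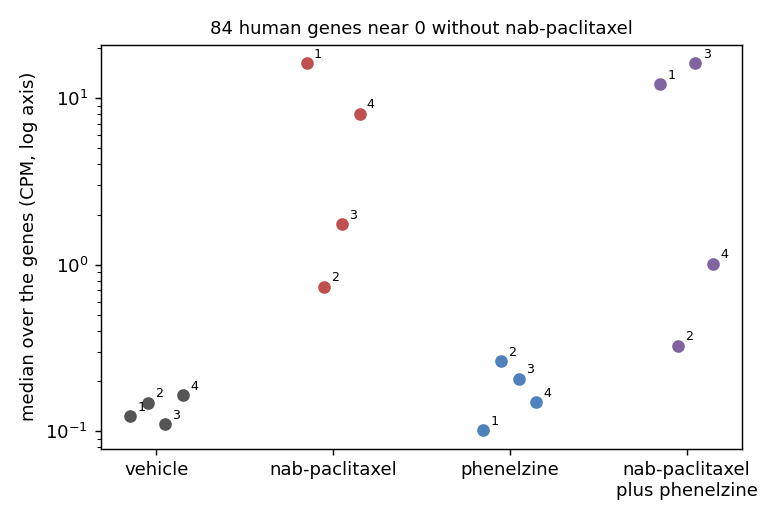
Median CPM (vertical log axis) of the 84 human genes near 0 in all libraries without nab-paclitaxel, for each library by treatment group, with points for single mice, numbered. The genes were chosen to be low without nab-paclitaxel, so those groups are low by definition; among libraries with it the median runs from 0.325 to 16.3 CPM.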

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

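Except for some fits, the tests in this part, regroupings of the libraries included, were given their bounds only after the results were seen. For the comparisons between groups, fits of only the 2 groups and fits with the mouse share as a covariate were fixed in advance. So was leaving out each library in turn. The averages of each drug and the leaving out of the 4 libraries that stand apart were added later. In 76 groups of 4 libraries tested for a library far from its group, 2 were found, where chance gives 3.8. The human total of phenelzine 4 was 30.23 M counts, against 33.91 to 34.54 M in the other libraries of its group. The mouse total of vehicle 2 was 14.41 M counts, against 5.211 to 6.382 M in the other vehicle libraries.

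The mouse share of counts averaged 42.4% in the 8 libraries with nab-paclitaxel and 16.9% in the 8 without. A few genes taking most of the counts is argued against: without the 100 highest genes of each matrix the difference was 24.7 points (exact permutation p = 0.00699, two-sided). A difference in the total count of both matrices is also argued against, since the difference was 27.4 points once the slope of the share on that total was removed (exact permutation p = 0.00373). How reads were divided between the species was not tested and stays open, as does an effect of the drug on the amount of tumour cells or host cells in the tissue. The pattern may therefore come from either.

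Human genes near 0 in every library without nab-paclitaxel and high in some with it numbered 84, against 41 at most in 99 other splits of the 16 libraries into 8 and 8. The definition was set after the real split was seen, which favours that split, so no conclusion on chance is drawn from this. Mouse reads counted on human genes at 1 rate in every library were not decided on. The count of these genes per mouse count differed by 52.7 times between libraries with nab-paclitaxel. That range rests on combination 2, which had by far the lowest value, and the other libraries with nab-paclitaxel differed much less. The genes were also chosen for being high in some of these same libraries, which widens the range. RNA of a further human profile, mixed in at a fraction that differs between libraries, could not be told apart from a graded response: by a margin of 10 percent in error, set after the first result, the models differed in 1 of 7 libraries, whereas by any difference in error the graded model was better in 6 of 7, which would have argued against mixing. A response of tumour cells to the drug that differs between mice stays open as a hypothesis, and whether RNA carried over between libraries was not decided.

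In the human genes, chance is argued against for nab-paclitaxel against vehicle, with 30 genes and at most 1 in another split. As many were called in 1 of 35 splits, the real one included. Chance is also argued against for the combination against vehicle (133 genes, at most 1 in another split, 1 of 35). The same holds for the combination against phenelzine (412 genes, at most 1, 1 of 35). A share of 1 in 35 is the smallest this test can give. It was not adjusted over the comparisons, so chance is not excluded. These verdicts hold for the fit over all 16 libraries. For the combination against vehicle and phenelzine, the fit of only the 2 groups called 0 and 1 of these genes. With the mouse share as a covariate, 1 and 3 genes passed in these 2 comparisons. The count for nab-paclitaxel against vehicle was 0 without vehicle 1. For the average of nab-paclitaxel, with 3131 genes, 1 of 100 regroupings gave as many, which argues against chance. That share is also the smallest possible. The highest other count there was 1672, in a regrouping that put vehicle 2, nab-paclitaxel 1, 3 and 4, phenelzine 2 and combination 1, 3 and 4 on 1 side. That side held 6 of the 8 libraries with nab-paclitaxel, the 4 that stood apart among them, so it in part follows that treatment.

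Chance cannot be excluded for the human genes of the combination against nab-paclitaxel: 6 of 35 splits gave the 1 gene of the real one or more. The highest, 6625 genes, set combination 1 and 3 and nab-paclitaxel 1 and 4 against the other 4 libraries, which points to a structure of the samples other than the treatment. With 0 human genes called by edgeR, every split gives as many for phenelzine against vehicle (35 of 35, highest other 2), for the interaction (100 of 100, highest other 2) and for the average of phenelzine (100 of 100, highest other 530). The regrouping behind the 530 genes put 7 of the 8 libraries with nab-paclitaxel on 1 side, so it nearly follows that treatment.

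In the mouse genes, chance is argued against for the average of nab-paclitaxel (120 genes, at most 4 in another regrouping, 1 of 100). This holds for the fit over all 16 libraries. With the mouse share as a covariate 1 gene passed, and 0 of the 120 were kept. The count was 0 without the 4 libraries that stood apart and 14 without nab-paclitaxel 1. For the combination against phenelzine the real split gave 1 gene and the other splits 0 (1 of 35), which rests on a single call. That call was lost with the mouse share as a covariate, without the 4 libraries that stood apart and in the fit of only the 2 groups. For the average of phenelzine, 3 of 100 regroupings gave the 4 genes of the real one or more, but a smaller draw made first did not exclude chance, so it is left open here. The highest count there, 144 genes, came from a regrouping with 5 of the 8 libraries with nab-paclitaxel on 1 side. It points to a structure of the samples that in part follows the first principal component of the mouse genes. The highest scores were all on that side (combination 1, 2 and 3, nab-paclitaxel 1 and 2 and vehicle 2, at 10.7 to 78.3). Vehicle 1 (-65.2) and phenelzine 3 (-22.5), also on it, went the other way. Chance cannot be excluded for the combination against vehicle, where 4 of 35 splits gave the 5 genes or more. The highest, 913, set combination 1, 2 and 3 and vehicle 2, with mouse shares of 71.2%, 47.4%, 55.9% and 37.8%, against the rest, with 13.6% to 19.0%. Nor can it be excluded for the combination against nab-paclitaxel, where 4 of 35 splits gave the 3 genes or more and the highest, 226, again set combination 1 and 3 and nab-paclitaxel 1 and 4 against the rest. Both point to a structure of the samples. With 0 mouse genes called by edgeR, every split gives as many for nab-paclitaxel against vehicle (35 of 35, highest other 1), for phenelzine against vehicle (35 of 35, highest other 0) and for the interaction (100 of 100, highest other 430). That last regrouping also had 5 of the 8 libraries with nab-paclitaxel on 1 side. Scores on the first principal component of the mouse genes ran from -8.6 to 78.3 on that side. They ran from -82.2 to 52.7 on the other, so the sides overlap and the structure of the samples was not settled.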

How the results depend on the processing

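Among the tests chosen only after the results were seen, this part gives the averages of each drug, the share of 8 against 8 libraries, the leaving out of the 4 libraries that stand apart (nab-paclitaxel 1 and 4, combination 1 and 3), the correlation of the nab-paclitaxel effects and the other bounds for the genes gained. The counts of human and mouse genes moved widely with single libraries and with the tool. Depth limits what low genes can show: the smallest mouse total was 3.46 M counts, and a count of 0 in the smallest combination library still allows 0.271 CPM of a human gene. The gene lists and the shares without mitochondrially encoded genes were not run, since no gene had a name. For each setting below the cause was not tested, except that fits of 2 groups or without libraries hold fewer samples. The largest shift of the median fold change of all genes under any setting was 0.05 on the log2 scale.

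Leaving out each library in turn gave 0 to 703 human genes for nab-paclitaxel against vehicle, 0 to 1 for phenelzine against vehicle, 1 to 1388 for the combination against vehicle, 0 to 1 for the combination against nab-paclitaxel, 7 to 1487 for the combination against phenelzine and 0 to 1 for the interaction. It gave 1855 to 4909 for the average of nab-paclitaxel and 0 to 1 for that of phenelzine. In the mouse genes it gave 0 to 4, 0 to 3, 0 to 58, 1 to 5, 1 to 389 and 0 to 4 for the same 6 comparisons in that order, 14 to 830 for the average of nab-paclitaxel and 4 to 8 for that of phenelzine. The libraries behind each value are named beside the comparisons.

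With DESeq2, human counts were 1441 for nab-paclitaxel against vehicle, 4 for phenelzine against vehicle, 1574 for the combination against vehicle, 10 for the combination against nab-paclitaxel, 1832 for the combination against phenelzine, 11 for the interaction and 8 for the average of phenelzine. Mouse counts were 221, 11, 325, 46, 563 and 18 for the same 6 comparisons, 1299 for the average of nab-paclitaxel and 23 for that of phenelzine. With voom and sample quality weights, human counts were 599 for nab-paclitaxel against vehicle, 0 for the combination against nab-paclitaxel and 126 for the combination against phenelzine. Mouse counts were 1 for nab-paclitaxel against vehicle, 3 for the combination against vehicle, 10 for it against nab-paclitaxel, 391 for it against phenelzine, 1 for the interaction, 898 for the average of nab-paclitaxel and 7 for that of phenelzine.

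Without a filter on low counts, human counts were 89 for nab-paclitaxel against vehicle, 1 for the interaction and 1 for the average of phenelzine, and mouse counts were 2 for nab-paclitaxel against vehicle, 2 for the combination against phenelzine and 63 for the average of nab-paclitaxel. With a minimum count of 50, mouse counts were 2 for nab-paclitaxel against vehicle and 186 for its average. With RLE size factors the mouse count for nab-paclitaxel against vehicle was 2.

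With the logit of the mouse share as a covariate, human counts were 16 for nab-paclitaxel against vehicle, 1 for the combination against vehicle, 3 for it against phenelzine and 27 for the average of nab-paclitaxel. Mouse counts were 1 for nab-paclitaxel against vehicle, 1 for the combination against vehicle, 1 for it against nab-paclitaxel, 0 for it against phenelzine and 1 for the average of nab-paclitaxel. The share differs between the groups, so this covariate takes out part of any treatment effect that goes with it. In fits of only the 2 groups compared, human counts were 1 for phenelzine against vehicle and 0, 0 and 1 for the combination against vehicle, nab-paclitaxel and phenelzine, and mouse counts for these last 3 were 0, 1 and 2, with 0 of the mouse genes called over all 16 libraries among them. Without the 4 libraries that stand apart, human counts were 21, 6 and 46 for the combination against vehicle, nab-paclitaxel and phenelzine, 4 for the interaction, 305 for the average of nab-paclitaxel and 4 for that of phenelzine. Mouse counts were 0, 0 and 0 for the combination against vehicle, nab-paclitaxel and phenelzine, 0 for the average of nab-paclitaxel and 1 for that of phenelzine.

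The sources used here do not say what a shared replicate number stands for. Deviations from the group means correlated over 0.1 in 4 of 24 same-numbered and 9 of 72 other pairs in the human genes, and in 11 of 24 and 26 of 72 in the mouse genes (median 0.097 against -0.009). All 4 same-numbered pairs of vehicle and phenelzine exceeded 0.1 in the mouse genes (0.113, 0.233, 0.266 and 0.240). This did not hold in the human genes of the same mice (-0.0418 to 0.104). Some differently numbered pairs of these groups were as high in the mouse genes. They were vehicle 3 with phenelzine 2 (0.290), 1 with 4 (0.279), 4 with 1 (0.211) and 2 with 3 (0.101). The rest were negative (-0.378 to -0.110). The values thus do not single out the shared number, and a pairing of these 2 groups stays open. The blocked count of mouse genes for phenelzine against vehicle was also 0 (edgeR, with 808 at an unadjusted p under 0.05). With the number as a block, human counts were 0 for nab-paclitaxel against vehicle, 10 for the combination against vehicle, 0 for it against nab-paclitaxel and 97 for it against phenelzine, and the mouse count for the combination against vehicle was 2. Within the same blocks, exact two-sided sign-flip tests of the mouse share gave p = 0.375 for nab-paclitaxel against vehicle, 0.25 for phenelzine against vehicle, and 0.125, 0.375 and 0.125 for the combination against vehicle, nab-paclitaxel and phenelzine; the smallest p they can give is 0.125.

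The differences in mouse share between groups kept their direction under each setting run. Leaving out 1 library gave 7.74 to 21.1 points for nab-paclitaxel against vehicle, -10.9 to -2.81 for phenelzine against vehicle, 19.6 to 37.1 for the combination against vehicle, 4.12 to 21.7 for it against nab-paclitaxel and 28.0 to 45.5 for it against phenelzine. For 8 libraries with nab-paclitaxel against 8 without, it gave 21.4 to 29.0 points with exact permutation p from 0.00280 to 0.0127. The difference for phenelzine in 8 against 8 libraries reversed without vehicle 1 (-0.462 points), vehicle 4 (-0.485), combination 1 (-4.14), combination 2 (-0.741) or combination 3 (-1.95); over all libraries left out it ran from -4.14 to 6.1.

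The fold changes of the 4 printed IDs kept their sign under each setting run. Across all settings the adjusted p for nab-paclitaxel against vehicle ran from 4e-11 (DESeq2) to 0.166 for ENSG00000137868 and from 1.84e-08 (DESeq2) to 0.0954 for ENSG00000204388. For the combination against phenelzine it ran from 3.57e-11 to 0.579 and from 9.17e-05 to 0.763 for these. For ENSMUSG00000055866 it ran from 2.25e-08 to 0.486 for the combination against vehicle and from 7.51e-11 to 1 for it against nab-paclitaxel. For ENSMUSG00000020522 it ran from 1.34e-11 to 0.690 for the combination against vehicle and from 2.77e-16 to 0.638 for it against phenelzine, the highest without the 4 libraries that stand apart. The correlation of the nab-paclitaxel effects with and without phenelzine was 0.692 to 0.792 in the human genes with 1 library left out and 0.333 without the 4 libraries that stand apart. In the mouse genes it was 0.0689 to 0.430 with 1 library left out, and without those 4 it reversed to -0.0179.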

Other observations

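All tests in this part were chosen only after the results were seen. In the host genes, the effects of nab-paclitaxel with and without phenelzine, from different libraries, correlated across genes with r = 0.227 (Spearman 0.275), genes not being independent replicates. This r was -0.0179 without the 4 libraries that stand apart, 0.0666 without a filter on low counts, 0.0689 without nab-paclitaxel 1, 0.0961 without vehicle 4, 0.126 without combination 3 and 0.430 without vehicle 2. The phenelzine effects with and without nab-paclitaxel correlated at -0.236. In the average effect of nab-paclitaxel, 58 of the 71 host genes that fell had a mean of at least 10 CPM without it, 9 host genes rose over 4-fold and 11 fell over 4-fold. Over all host genes tested, the libraries of the 2 sides did not overlap in 49, or 0.325%, against 0.016% by chance.

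The 84 human genes near 0 without nab-paclitaxel took 0.288%, 0.0133%, 0.0236% and 0.130% of the human counts in nab-paclitaxel 1 to 4, and 0.201%, 0.00395%, 0.293% and 0.0135% in combination 1 to 4. The second principal component of the human genes held 6.73% of the variance, and combination 2 scored -71.4 on it.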
